A study of Gossypium hirsutum with 18 samples.

How the data were processed

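RNA was measured in meristems dissected from cotton apices, 18 libraries in 7 groups, each group defined by the virus the plants received. Per the labels' protocols, apices were kept in acetone, meristems were dissected under a stereomicroscope, frozen and homogenised, and RNA was extracted with hot borate followed by column clean-up. Libraries were made from 20 ng of RNA with a low-input kit and sequenced for 75 cycles on a NextSeq instrument, per the labels' protocols. The labels call the libraries of a group biological replicates.

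The values analysed here come from 1 table of the authors' own comparisons. Per the file headers, it lists for a transcript and a pair of groups a fold change, a direction, the sum of the FPKM of both groups, and a q-value. The fold is a ratio that the authors deposited without sign, the larger over the smaller group value. FPKM (fragments scaled to transcript length and to the mapped fragments of a library) was computed by the authors, per the file headers. The q-value is the adjusted p-value of the authors' test, per the file headers. The test, the aligner, the genome build and the annotation source are not given in the sources used here. The submitters' processing notes name FastQC, a read quality tool, with no version. The transcript identifiers end in a version suffix that marks a gene model release.

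The table held 18900 entries for 6332 transcripts of 6329 genes, and all 21 pairs of the 7 groups were present. Every q-value in the authors' deposited table was below 0.05, from 0.00476 to 0.0486. A transcript without an entry for a pair may have been tested without passing, not tested, or left out after passing, and these cases cannot be separated. Folds ranged from 1.64 to 119.12 in the authors' deposited table, and the sum of both FPKM values from 1.82 to 6740.14. The table gives no value per library. The depth of each library is therefore unknown, and no SD, test between libraries, comparison of replicates or pairing of replicate numbers could be computed. The plan fixed before the data were examined for such a table was to describe the authors' values with no further test of the differences between groups, and that was followed. Tests on lists of the authors' calls, such as those of identifiers and subgenomes, were added to it. The planned model fits, their alternatives and the omission of single libraries all need values per library and were not run.

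The FPKM of each group was recovered from the sum and the fold of an entry: the smaller value is the sum divided by the fold plus 1. A total of 23127 group values were recovered, and 664 transcripts had a value in all 7 groups. For 8368 of these values, more than 1 entry gave the same quantity, and the entries differed by at most 0.378%. The recovery was tested on simulated data for 6253 transcripts with sums in the range of the table, where the largest error was 0.334%. A recovered FPKM is the authors' group value and comes with no error estimate over libraries.

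The deposited table fills its description column in 0 entries, and the files do not pair the identifiers with gene names. A table of 99454 RefSeq genes of the assembly Gossypium_hirsutum_v2.1 was searched for them, and 0 of the 6329 genes matched. The silenced genes therefore could not be looked up, and the 30 gene lists fixed before the data were examined, which hold silencing targets, meristem, flowering, hormone and cell cycle genes and markers of other tissues, could not be scored. The rule fixed for naming genes required a description and libraries that do not overlap, and so named none. In its place, at most 2 identifiers per direction are given for a comparison, those with the largest fold. For sets over several comparisons, those with the largest of the smallest folds are given. This replacement was chosen after the table was seen, as were all sets over several comparisons, the partitions of groups, the tests on identifiers and subgenomes, the simulated overlaps and the reading of the q-values.

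Counts of called transcripts per comparison and direction were taken as deposited. Comparisons against the same group share its libraries, so overlaps of calls were set beside 2 reference values. The first is the overlap of independent lists of the same sizes. The second comes from 1000 simulated draws in which all groups hold noise alone and share the libraries of the common group. These draws give every transcript and library the same spread, which cannot be checked here. Both reference values used the 6332 transcripts of the table as the number tested. The number the authors tested is not given in the sources used here, and a larger number would lower both values. For the transcripts higher in SP and the sets over all groups, both were therefore also computed with 2 and 5 times as many transcripts taken as tested, with 200 draws each. TRV has 2 libraries, and the table has no library values, so the controls could not be split. Part of any excess may therefore come from the shared controls. On simulated independent lists drawn from 6332 transcripts, the simulated overlap was 0.999 times the expected one.

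Shares were compared with Fisher's exact test, subgenome balance with exact binomial tests, both two-sided, and the closeness of identifiers with 10000 random sets, one-sided. Families of tests were adjusted by the Benjamini-Hochberg method. In simulated random sets from 3000 transcripts, 1.5% had p under 0.05 in the test of closeness. The alternatives were a q-value under 0.01, a sum of both FPKM values of at least 20, and the removal of identifiers whose number is not a multiple of 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.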

Results

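Gene expression was profiled in shoot meristems of upland cotton (Gossypium hirsutum, genotype Coker 312) after virus-induced gene silencing, in which a virus that carries a piece of a plant gene directs the plant's RNA silencing against that gene. Tobacco rattle virus (TRV) was delivered by Agrobacterium into the cotyledons 4 days after germination. Apices were harvested 15 days after infection, 19 days after germination. The control group received TRV with no plant target named (TRV, 2 libraries). The SP group received TRV aimed at SELF-PRUNING, a relative of TERMINAL FLOWER 1 that keeps shoot growth indeterminate (3 libraries). In the other groups SELF-PRUNING was silenced together with a second gene. These were CLAVATA1 (SP-CLV1, 3 libraries), a receptor kinase; CLAVATA2 (SP-CLV2, 3 libraries), a receptor-like protein; CLAVATA3 (SP-CLV3, 3 libraries), the precursor of a secreted peptide; a gene labelled FIN (SP-FIN, 2 libraries); and PERIANTHIA (SP-PAN, 2 libraries), a bZIP transcription factor. The CLAVATA genes restrict the stem cell population of the meristem through WUSCHEL. The series asked how silencing of genes in this circuit changes meristem transcription.

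All values below are from the authors' deposited table of significant comparisons, which has 1 value per pair of groups and none per library. Folds, FPKM and q-values are therefore given without an error of their own, and the q-value stands for the authors' test over the libraries of both groups. The transcripts of SELF-PRUNING, the CLAVATA genes, FIN and PERIANTHIA could not be located by name, so the extent of silencing in each group was not analysed here. Of the 6332 transcripts called in at least 1 of the 21 pairs of groups, 3130 lay on chromosomes of the A subgenome, 3190 on those of the D subgenome and 12 on unplaced scaffolds. The recovered group levels of these transcripts had a median of 14.9 FPKM and ranged from 0.175 to 4852.15 FPKM.

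Silencing of SELF-PRUNING alone was compared with the virus control first. Most changed transcripts rose: in the authors' deposited table, a total of 1093 were higher and 303 lower in SP than in TRV, so 78.3% of the 1396 calls were increases. The decreases had larger folds, with a median of 3.22 (interquartile range 2.64 to 4.91) against 2.83 (2.44 to 3.53) for the increases, and 24 decreases but 9 increases reached 10-fold. Transcripts that rose were also more abundant, with a median sum over both groups of 78.7 FPKM against 25.1 FPKM for those that fell. The largest increase in the authors' deposited table was that of Gohir.D10G032100 on chromosome D10, from 1.5 FPKM in TRV to 26.4 FPKM in SP (17.59-fold, q = 0.00843). Gohir.A03G176400 on A03 followed, from 4.58 to 75.8 FPKM (16.54-fold, q = 0.00843). The largest decrease was that of Gohir.1Z049999 on an unplaced scaffold, from 17.99 to 0.819 FPKM (21.97-fold, q = 0.0258). Gohir.A06G098102 on A06 fell from 82.4 to 4.93 FPKM (16.70-fold, q = 0.0350 in the authors' deposited table). At a q-value under 0.01, 627 calls were left, and every other comparison with TRV or SP also lost calls by more than 1.5 times.

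The groups in which a second gene was silenced with SELF-PRUNING were compared with the same TRV control. SP-PAN differed most, with 1441 transcripts higher and 798 lower than in TRV in the authors' deposited table. SP-CLV3 (725 higher, 492 lower) and SP-CLV2 (761 higher, 450 lower) had about as many calls as SP, with a smaller share of increases. SP-FIN had 461 higher and 327 lower. SP-CLV1 differed least, with 207 higher and 195 lower, a share of 51.5% increases. This share was 46.9% at a q-value under 0.01, 59.7% with a sum of both FPKM values of at least 20, and 59.6% without identifiers whose number is not a multiple of 100. Decreases had the larger median fold in each of these groups too, from 3.21 in SP-PAN to 3.75 in SP-CLV1, against 2.52 in SP-CLV3 to 2.75 in SP-PAN for increases. The decreases also had the lower median sum of both FPKM values in each, for example 24.8 against 69.8 FPKM in SP-PAN and 37.5 against 40.6 FPKM in SP-FIN. Identifiers whose number is not a multiple of 100 made up 13.2% to 33.3% of the decreases and 4.09% to 7.25% of the increases. Whether the larger folds follow from either was not tested. Whether the groups differ in the number of changed transcripts was not tested, and groups of 2 libraries are compared with groups of 3.

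Several transcripts led these comparisons in more than 1 group. Gohir.D04G190300 on D04 was the strongest increase in SP-CLV1 (12.22-fold, q = 0.00476) and in SP-FIN (16.08-fold, q = 0.00476), rising from 2.25 FPKM in TRV to 27.5 and 36.2 FPKM in the authors' deposited table. Gohir.D13G084400 on D13 was the strongest in SP-CLV2 (31.91-fold, q = 0.0399), SP-CLV3 (24.70-fold, q = 0.0350) and SP-PAN (34.53-fold, q = 0.0399). It rose from 1.16 FPKM in TRV to 37.0, 28.6 and 40.04 FPKM, and the authors' deposited table has no entry for it in SP, SP-CLV1 or SP-FIN. Among decreases, Gohir.A13G092605 on A13 fell from 80.9 to 2.33 FPKM in SP-CLV1 (34.72-fold, q = 0.0215). Gohir.A05G070700 on A05 fell from 48.4 to 1.24 FPKM in SP-CLV3 (38.96-fold, q = 0.0168 in the authors' deposited table), while its level was 46.5 FPKM in SP.

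All silenced groups carry the SELF-PRUNING insert, and the transcripts changed in every one of them against TRV were counted. By the authors' deposited table, a total of 60 were higher and 65 were lower than TRV in all 6 silenced groups. Simulated groups that hold noise alone and share the TRV libraries gave a mean of 36.0 (18 to 54 over 1000 draws) for the higher and 15.2 (4 to 27) for the lower set. Independent lists of these sizes would share 0.00815 and 0.000335. Part of the excess over independent lists may come from the shared controls, which could not be split. Of the lower set, 66.2% had an identifier whose number is not a multiple of 100, against 3.33% of the higher set. Without such identifiers the lower set held 22, where noise alone gave a mean of 10.04 and at most 20, and the higher set held 58, where it gave at most 53. In the higher set the median level rose from 21.1 FPKM in TRV to 59.0 FPKM in SP-CLV1, the lowest of the silenced groups, and to 118 FPKM in SP-PAN, the highest. In the lower set it was 57.4 FPKM in TRV and between 8.21 FPKM in SP-PAN and 12.8 FPKM in SP. Gohir.A10G185100 on A10 stood at 10.8 FPKM in TRV and at 78.8 to 122 FPKM in the silenced groups. Gohir.A01G126732 on A01 stood at 40.7 FPKM in TRV and at 1.42 to 3.01 FPKM in the silenced groups.

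**Figure D1:**
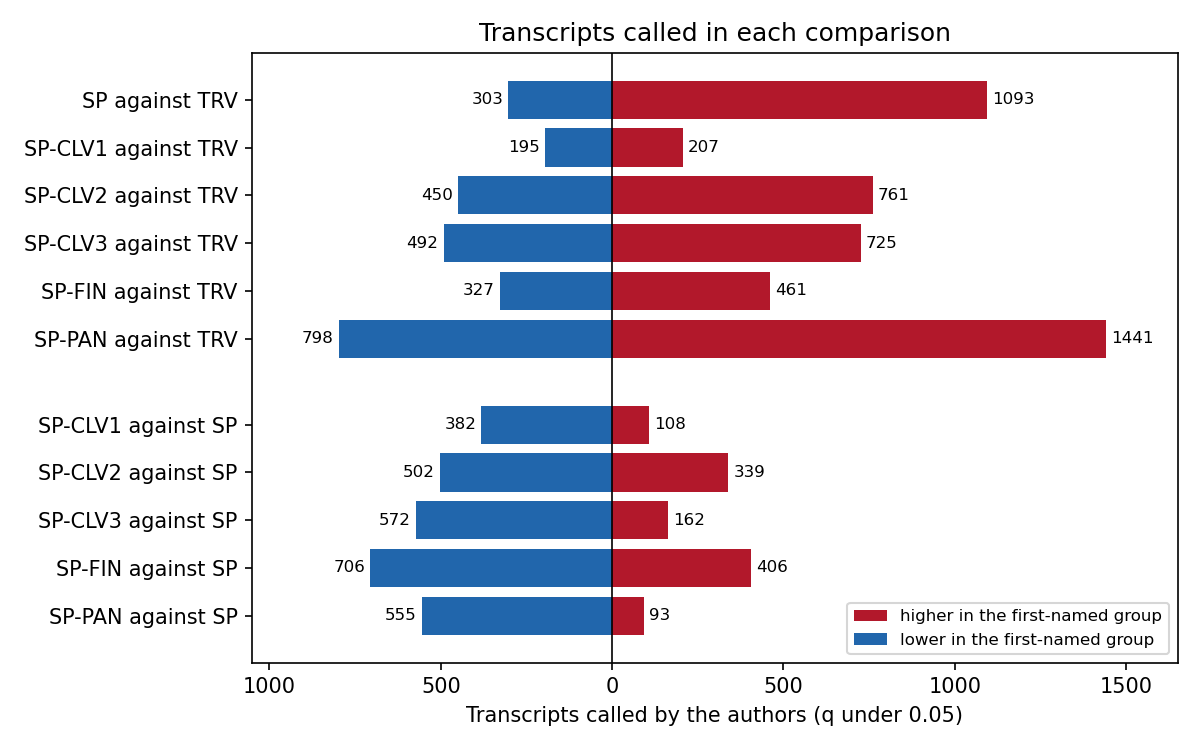
Bars give the number of transcripts the authors called at q under 0.05 in each of 11 comparisons, to the right for transcripts higher and to the left for those lower in the first-named group. Increases outnumber decreases in the 6 comparisons with TRV (from 207 against 195 in SP-CLV1, where the order turned at a q-value under 0.01, to 1441 against 798 in SP-PAN), and decreases outnumber increases in the 5 comparisons with SP. The comparisons with TRV share its libraries, and those with SP share the SP libraries.

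Calls against TRV that SP and a co-silenced group have in common were counted per direction. SP-PAN had the most: 835 of the 1093 transcripts higher in SP (76.4%) were also higher in SP-PAN, where noise with shared controls gave at most 617 and independent lists 249. The corresponding numbers from the authors' deposited table were 488 for SP-CLV3, above the simulated maximum of 426, and 435 for SP-CLV2, equal to its simulated maximum of 435, with 125 and 131 for independent lists. They were 240 for SP-FIN and 140 for SP-CLV1. With only the listed transcripts taken as tested, this was about what noise alone gave (means of 251 and 142, at most 281 and 161), while independent lists would share 79.6 and 35.7. These references depend on the number of transcripts tested, which is not known. With 2 times the listed number noise gave at most 230 and 135, and with 5 times at most 166 and 110, all below the counts. Whether SP shares increases with these groups beyond noise therefore stays open. Of the 303 transcripts lower in SP, 200 were also lower in SP-PAN, 167 in SP-CLV3, 156 in SP-CLV2, 142 in SP-FIN and 120 in SP-CLV1. Each of these exceeded its simulated maximum, which ran from 87 in SP-CLV1 to 174 in SP-PAN, and independent lists would share 9.33 to 38.2. Of 3203 transcripts called against TRV in at least 1 silenced group, 9 were higher in 1 group and lower in another.

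The co-silenced groups were next compared with SP. A difference from SP may come from the second target or from weaker silencing of SELF-PRUNING, and neither was tested. All of these comparisons share the SP libraries, so noise in those libraries would enter each of them. In these comparisons most calls were decreases. In the authors' deposited table, a total of 382 transcripts were lower and 108 higher in SP-CLV1 than in SP, 502 and 339 in SP-CLV2, 572 and 162 in SP-CLV3, 706 and 406 in SP-FIN, and 555 and 93 in SP-PAN. SP-FIN thus had the most calls (1112) and SP-CLV1 the fewest (490). With a sum of both FPKM values of at least 20, SP-FIN still had the most (800), but SP-PAN had fewer (412) than SP-CLV1 (426), and the share of increases fell from 40.3% to 22.5% in SP-CLV2 and from 36.5% to 21.5% in SP-FIN. Decreases of at least 10-fold were frequent in SP-PAN (48), SP-CLV3 (44) and SP-CLV2 (28), against 10 in SP-FIN and 1 in SP-CLV1, while increases of that size numbered 3 or fewer in each group.

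The largest fold of the whole table was a decrease in this family. Gohir.D05G363800 on D05 fell from 208 FPKM in SP to 1.74 FPKM in SP-PAN (119.12-fold, q = 0.00476 in the authors' deposited table) and to 5.04 FPKM in SP-CLV2 (41.25-fold, q = 0.00476). It stood at 98.1 FPKM in SP-CLV1, 107 FPKM in SP-FIN and 17.2 FPKM in TRV, and no entry gives its level in SP-CLV3. Gohir.A11G163300 on A11 fell from 131 FPKM in SP to 2.13 FPKM in SP-CLV3 (61.26-fold, q = 0.00476 in the authors' deposited table). In SP-FIN the largest decrease was that of Gohir.A05G290900 on A05, from 93.8 to 1.68 FPKM (55.91-fold, q = 0.0366). In SP-CLV1 it was that of Gohir.A03G176400, from 75.8 to 5.15 FPKM (14.71-fold, q = 0.00476 in the authors' deposited table), and its level in TRV was 4.58 FPKM. Among increases, Gohir.A01G137734 on A01 rose from 1.53 FPKM in SP to 19.9 FPKM in SP-CLV3 (12.99-fold, q = 0.0258), 23.5 FPKM in SP-FIN (15.38-fold, q = 0.0486) and 26.2 FPKM in SP-PAN (17.11-fold, q = 0.0399). Its level in SP-CLV2 was 0.796 FPKM. Gohir.D01G179700 on D01 rose from 6.10 to 102 FPKM in SP-FIN (16.77-fold, q = 0.00476 in the authors' deposited table). Its level was 41.1 FPKM in TRV and 16.2 to 36.0 FPKM in the other co-silenced groups, so SP was the lowest.

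In all 5 co-silenced groups against SP, 17 transcripts were lower and 4 higher in the authors' deposited table. Noise in the shared SP libraries alone gave a mean of 20.1 (8 to 34) for the lower and 2.09 (0 to 8) for the higher set, so neither count lay outside the simulated range, and independent lists would share 0.0267 and 0.000139. With 5 times as many transcripts taken as tested, noise gave at most 11 and 4. Gohir.A02G119200 on A02 stood at 23.4 FPKM in SP, 6.99 FPKM in TRV and 1.198 to 5.40 FPKM in the co-silenced groups. Gohir.D10G221300 on D10 stood at 25.3 FPKM in SP and 49.3 to 67.3 FPKM in the co-silenced groups.

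The co-silenced groups were also compared with each other. SP-PAN and SP-FIN differed in 1725 transcripts and SP-PAN and SP-CLV1 in 1221, the highest numbers of the 10 such pairs in the authors' deposited table. SP-CLV2 and SP-CLV3 differed in 372, the lowest. For 32 transcripts each of SP, SP-CLV1 and SP-FIN was called above each of SP-CLV2, SP-CLV3 and SP-PAN, which takes 9 calls. Of the 20 ways to set 3 of the 6 silenced groups above the other 3, the rest gave at most 2. Over all 62 ways to set some of these groups above the others, SP-PAN below the other 5, which takes only 5 calls, came next with 31. At a q-value under 0.01 both gave 13, and with a sum of both FPKM values of at least 20 they gave 16 and 23. With that sum, SP and SP-CLV1 above the other silenced groups (8 calls) gave 20, and SP above the other 5 (5 calls) also gave 16. Splits that need fewer calls are easier to meet, so these counts are not on equal terms. The medians of these 32 transcripts were 23.5 FPKM in SP, 20.9 FPKM in SP-CLV1 and 22.1 FPKM in SP-FIN, against 3.60 FPKM in SP-CLV2, 2.12 FPKM in SP-CLV3 and 3.43 FPKM in SP-PAN. For the 27 with a TRV value, the median fold over TRV was 1.44 in SP (interquartile range 1.18 to 3.23), 1.29 in SP-CLV1 (0.829 to 1.75) and 1.36 in SP-FIN (0.759 to 1.97), and 6, 1 and 4 transcripts were called above TRV and 0 below. The authors' deposited table calls 18 of the 32 below TRV in SP-CLV2, 15 in SP-CLV3 and 19 in SP-PAN. Gohir.A04G023500 on A04 stood at 43.5 FPKM in TRV, at 102, 79.2 and 66.4 FPKM in SP, SP-CLV1 and SP-FIN and at 6.06, 1.84 and 4.92 FPKM in SP-CLV2, SP-CLV3 and SP-PAN.

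**Figure D2:**
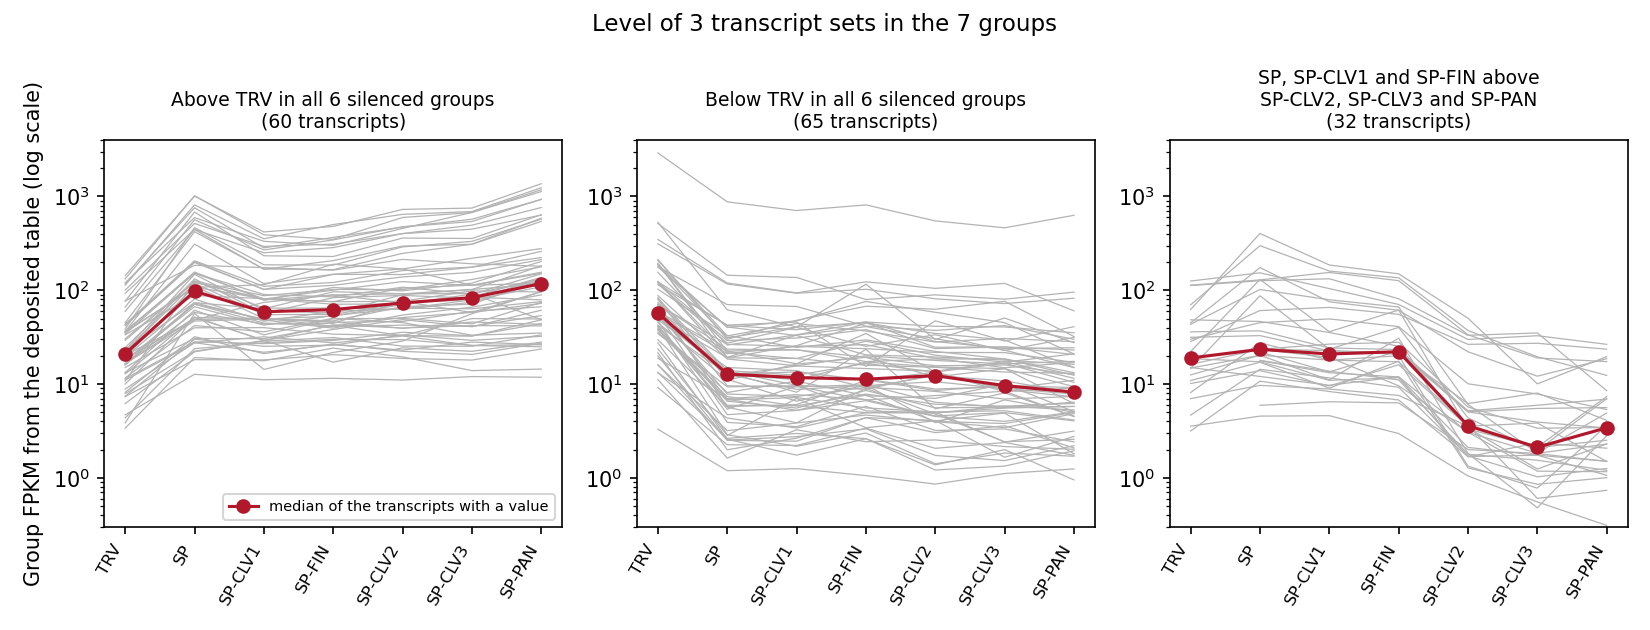
Each grey line follows 1 transcript over the 7 groups, as group FPKM on a log axis, and the red points are medians of the transcripts with a value. The left panel holds the 60 transcripts above TRV and the middle panel the 65 below TRV in all 6 silenced groups. The right panel holds the 32 transcripts chosen because each of SP, SP-CLV1 and SP-FIN was called above each of SP-CLV2, SP-CLV3 and SP-PAN. That choice fixes the order of their medians, 2.12 to 3.60 FPKM in SP-CLV2, SP-CLV3 and SP-PAN and 20.9 to 23.5 FPKM in SP, SP-CLV1 and SP-FIN.

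Cotton is an allotetraploid, and the calls were split by subgenome. The A subgenome held 43.5% to 56.7% of the transcripts placed on chromosomes over the 11 comparisons and both directions. None of the 22 exact binomial tests against an equal split passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.427), and 2 had an unadjusted p under 0.05.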

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

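All tests in this part were chosen after the results were seen.

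Transcripts higher in SP than in TRV and lower again in a co-silenced group were counted, because the authors called the difference between the 2 silenced groups directly. Of the 1093 transcripts higher in SP than in TRV, 232 were lower in SP-CLV1 than in SP, 111 in SP-CLV2, 118 in SP-CLV3, 275 in SP-FIN and 56 in SP-PAN. Independent lists would share 65.9, 86.7, 98.7, 122 and 95.8 in that order. At most 2 of them were higher still in a co-silenced group. Noise in the SP libraries, which enter both comparisons, would give such a return too. Simulated noise alone gave a mean of 182 and at most 209 for SP-CLV1, and 274 and at most 317 for SP-FIN, so 1 of the 5 counts, that of SP-CLV1, lay above the simulated range. The counts of the other 3 groups lay below their simulated means (226 for SP-CLV2, 251 for SP-CLV3 and 226 for SP-PAN). These references rest on the 6332 listed transcripts as the number tested, which is not known. With 5 times as many, noise alone gave at most 107 for SP-CLV1 and 150 for SP-FIN, both below the counts, and a mean of 102 for SP-PAN, above its count. The simulation also gives every library the same spread, which the table cannot check, so shared noise stays open. The number of libraries in the co-silenced group cannot alone account for the spread of the counts, since SP-FIN and SP-PAN have 2 each and differ by 4.91 times. That number may still contribute. An effect of the second silenced gene, or weaker silencing of SELF-PRUNING where 2 targets share a virus, may contribute as well, and neither was tested.

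For 9 transcripts the direction against TRV was opposite between silenced groups, which the authors' test of each group against TRV shows. The authors' deposited table also calls every such pair of groups different from each other, but opposite calls against TRV nearly fix that outcome. One of them, Gohir.A11G163300, was chosen after its values were seen: it was higher than TRV (22.2 FPKM) in SP (131 FPKM) and SP-FIN (61.6 FPKM) and lower in SP-CLV2 (3.31 FPKM). It stood at 2.13 FPKM in SP-CLV3, 7.36 FPKM in SP-PAN and 36.2 FPKM in SP-CLV1, with no call against TRV in these groups. The decrease is therefore not particular to SP-CLV2.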

How the results depend on the processing

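All alternatives in this part were chosen after the data were seen. No paired analysis was possible because the deposited table has 1 value per pair of groups and no library values, and the planned fits, normalizations, filters and omissions of single libraries were not run for the same reason. The depth of each library is unknown, so the limit it sets on the calls could not be given. At a q-value under 0.01, against TRV, 627 calls were left in SP, 147 in SP-CLV1, 476 in SP-CLV2, 512 in SP-CLV3, 292 in SP-FIN and 1090 in SP-PAN; against SP, 165 in SP-CLV1, 296 in SP-CLV2, 333 in SP-CLV3, 405 in SP-FIN and 319 in SP-PAN. At that threshold 52 transcripts differed from TRV in all silenced groups, 4 from SP in all co-silenced groups, and 2818 in any pair. A stricter threshold can only remove calls. The share of increases in SP-CLV1 against TRV turned from 51.5% to 46.9%, while the 2 alternatives described next gave 59.7% and 59.6%; at this threshold the other 10 shares stayed on their side of 50%. With a sum of both FPKM values of at least 20, which also only removes calls, 484 were left for SP-CLV2 against SP, 412 for SP-PAN against SP and 4076 for any pair. That filter lowered the share of increases against SP from 40.3% to 22.5% in SP-CLV2 and from 36.5% to 21.5% in SP-FIN, so low transcripts held many of the increases. Without identifiers off the grid of 100, 80 of the 125 transcripts that differ from TRV in all silenced groups were left, and the lower set shrank from 65 to 22. The set of 32 transcripts that separates SP, SP-CLV1 and SP-FIN from the other silenced groups held 13, 16 and 31 under these 3 alternatives.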

Other observations

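All tests in this part were chosen after the results were seen.

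Of the co-silenced groups, SP-PAN and SP-FIN stood apart from all other silenced groups most often, and they are also the silenced groups with 2 libraries in place of 3, so the number of libraries and the second target are not separated here. In the authors' deposited table, a total of 31 transcripts were lower in SP-PAN than in each of the other 5 silenced groups, and 27 of all transcripts were lower in SP-PAN than in all other 6 groups, TRV included. SP-FIN was above each of the other 5 silenced groups in 26 transcripts and below them in 15. The count of 26 was no longer among the 4 highest of the 62 splits at a q-value under 0.01 or with a sum of both FPKM values of at least 20. Apart from TRV, no other group lay below all other 6 groups in more than 4 transcripts or above them in more than 8. Counts of this kind were looked up for all 62 splits of the silenced groups, so the highest ones are partly selected.

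Transcripts lower than TRV often had identifiers that do not follow the numbering of the annotation, in which most gene numbers are multiples of 100. Such identifiers made up 6.54% of all transcripts, but 43 of the 65 (66.2%) that were lower and 2 of the 60 (3.33%) that were higher than TRV in all 6 silenced groups (odds ratio 56.7, Fisher's exact p = 1.18e-14). For transcripts called in at least 1 group the shares were 12.6% of 1137 and 4.28% of 2057 (Fisher's exact p = 4.07e-17). The level of expression alone does not account for this, since the lower transcripts had the higher share in 3 of 4 classes of mean FPKM at an adjusted Fisher's exact p under 0.05, with 0.54 in the lowest class. Runs of adjacent gene models, between which reads can be shared, are present: 12 pairs of identifiers among the 61 placed transcripts of the all-group lower set were at most 1000 apart, where 10000 random sets had at most 9 (permutation p = 0.0001, the smallest they can give). Over transcripts called in at least 1 group such pairs exceeded the random median in both directions, with 231 against 194 for the lower (permutation p = 0.0012) and 623 against 582 for the higher (permutation p = 0.0071). Among transcripts called in at least 1 group, those with no such neighbour in their set still had a share of 7.60% against 4.13% (Fisher's exact p = 0.00282). In the all-group sets the shares without such neighbours were 21 of 40 (52.5%) for the lower and 2 of 56 (3.57%) for the higher (Fisher's exact p = 2.43e-08). Adjacent gene models outside the set were not looked at, so this does not exclude shared reads as the whole cause. Also open is whether the TRV libraries held RNA of another composition or whether SELF-PRUNING silencing lowered the transcripts with such identifiers. The share was 13.2% to 33.3% among transcripts lower than TRV and at most 9.80% in the comparisons without TRV, and TRV is the only group without the SELF-PRUNING insert, so these cannot be told apart.

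The ladder of q-values hints at entries that the table does not hold. The 23 distinct q-values were read as equal steps of p under Benjamini-Hochberg adjustment over 1 pool of tests. The last 12 steps then imply 10807 tests at the lowest q-value (interquartile range 10457 to 10839), where the authors' deposited table has 6408. Over all q-values 18900 entries stand against 24316 implied, or 77.7%. A candidate explanation is that comparisons in which 1 group had no detected expression were left out, since 0 entries have a group at 0 FPKM. If so, transcripts switched fully on or off between groups are missing from every count given here. The pool and the equal steps are assumptions, and other filters could give the same deficit.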
